A study of Mus musculus with 10 samples.

How the data were processed

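The series holds droplet-based single-cell RNA sequencing (10x Genomics 3′ chemistry) of tdTomato-labelled cells sorted from mouse pancreata at E15.5. Neurog3-Cre marks and recombines cells that enter the endocrine lineage. The labels give 3 genotypes, all carrying the tdTomato reporter: control (1 floxed and 1 intact Brg1 allele, 1 intact Brm allele; 3 libraries), Brg1Δendo;Brm+/- (both Brg1 alleles floxed, 1 intact Brm allele; 4 libraries) and DKOΔendo (both Brg1 alleles floxed, no intact Brm allele; 3 libraries). Brg1 is the product of Smarca4 and Brm that of Smarca2, the alternative ATPases of the Swi/Snf chromatin remodelling complex. Sources were the labels, the series title and design text, the deposited count matrices and a gene annotation of the GRCm38 build.

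The authors deposited one matrix of counts per library: unnormalised UMI counts per gene and cell barcode, over 32285 genes. The submitters' processing notes name Cell Ranger 5.0.1, STAR, bcl2fastq, Seurat 4.3.0.1 and the mm10 build; the step that used Seurat is not given in the sources used here. Control replicate 1 and Brg1Δendo;Brm+/- replicate 1 were deposited as unfiltered matrices with 333967 and 237738 barcodes. The other 8 matrices hold the barcodes called as cells. The barcode and gene name files hold names only and are of an other kind than measurements, per the labels and the file contents.

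The same cell filter was applied to every library: at least 2000 UMIs, at least 1000 genes, and at most 10% of UMIs from mitochondrial genes. The mitochondrial limit removed from 0.909% (Brg1Δendo;Brm+/- replicate 1) to 19.7% (DKOΔendo replicate 3) of the barcodes with at least 2000 UMIs. Of 4975 barcodes that passed, Scrublet (scanpy 1.11.5, automatic threshold per library) called 53 doublets, between 0.232% and 6.67% per library, which were removed, leaving 4922 cells. Cells were normalised to 10000 UMIs, log-transformed, and clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 (igraph 0.11.9, fixed seed), with no batch integration. Clusters were named from 14 marker lists: a cluster took the name of a list with at least 3 markers that had a log2 fold of at least 1 over other cells and UMIs in at least 25% of its cells. Those 3 naming thresholds were set after a first look at the clusters. The endocrine lineage comprises the progenitor, precursor, alpha, beta, delta, epsilon, and ductal and trunk-like clusters. Acinar, mesenchymal, endothelial, blood, immune and neural crest-like cells were left out of it, since the comparisons concern endocrine cells.

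UMIs were summed per library, so that libraries and not cells are the replicates. Sums were made over the endocrine lineage and over each class for libraries with at least 10 cells of it. Only the 4 classes fixed beforehand (endocrine progenitor, Fev precursor, alpha and beta-like cells) were tested gene by gene; delta and epsilon-like cells entered as shares and for Smarca4. The sums were fitted with edgeR 4.0.16 (R 4.3.3; TMM normalisation, filterByExpr, quasi-likelihood F test, all libraries in 1 fit) and Benjamini-Hochberg adjustment at 0.05 within each contrast. "Called" means an adjusted p under 0.05. Levels are CPM, counts scaled by the effective library size, given as mean ± SD over libraries, and log2 fold changes as estimate ± SE. Class shares were compared by an exact permutation test over all 4200 regroupings of the 10 libraries, two-sided for pairs of groups. The smallest p for 3 against 3 libraries is 0.1 and for 4 against 3 is 0.0286. The 28 fixed lists (14 cell type lists and 14 gene groups) were tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01, adjusted over the lists per contrast), again with an estimated correlation, and with fry; single members were adjusted over all genes and over the list alone. Only lists the text needs are named. Their number and that of the lists left out are given with the dependence on processing.

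Genes named in the text follow a rule fixed before the data were examined. For lineage contrasts the rule takes Smarca4 and Smarca2, up to 6 called genes with the highest and 6 with the lowest log2 fold change (mean log2 CPM of at least 5, no overlap between the groups' libraries), and the member with the smallest p of each of 8 lists where none was called. For class contrasts it takes the 5 highest and 5 lowest by the same size rule. Sex-linked genes and gene models without a standard symbol are excluded. Genes named outside the rule are marked as chosen after their values were seen. The gene lists, groups, tests, cell filter and most processing alternatives were also fixed before the data were examined.

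Alternatives fixed beforehand were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a replicate block, leaving out each library, leaving out both libraries deposited unfiltered, a stricter cell filter (5000 UMIs, 2000 genes, 5% mitochondrial), doublets kept, equal cell numbers, all cells in place of the lineage, Leiden resolution 0.6, clustering without marker and list genes, and classes taken from the nearest control cells. Chosen after the data were seen were islet classes without ductal and trunk-like cells, a limma voom fit of sums per class and library with class as a term and library as a random block (52 sums), a sex term, and the alternatives of the list tests with an estimated correlation. Sex was read from Xist and Ddx3y: control 1, Brg1Δendo;Brm+/- 2, DKOΔendo 1 and DKOΔendo 3 were male, so sex is unevenly spread over the genotypes. The replicate numbers do not pair the libraries: over 9 pairs of the same number, residual correlations ran from -0.196 to 0.143. No 2 replicates of a group are repeats of 1 library, since counts differed far beyond sampling noise (chi-square per degree of freedom from 11.7 to 58.5 over 12 pairs).

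The edgeR fits were tested on simulated data with the real libraries' depth and spread. Across 11 contrasts they recovered between 36.1% and 68.7% of genes changed 2-fold and between 84.0% and 98.9% of genes changed 4-fold, with 6 to 13 false calls each. On simulated lists of 20 genes, camera found the changed list and called 0 other lists. The simulated genes varied independently, so this does not test how often camera calls lists of correlated genes falsely. For DKOΔendo against control, the class-term fit made 61 false calls among 12810 simulated genes. It recovered 87 of 100 genes changed 2-fold and 95 of 100 changed 4-fold. The DESeq2 fit made 20 false calls among 13938 and recovered 72 of 99 and 87 of 98. Set against the genes recovered, false calls were a larger share of all calls than the threshold allows in both fits. Genes called only by these fits are therefore less certain than their adjusted p states. Figures were drawn with matplotlib 3.10.9, and exact tests and 95% Clopper-Pearson intervals computed with scipy 1.17.1. Intervals of shares of cells, and floors of 3 counts beside values of 0, cover counting error only. Intervals beside median shares of a log2 fold change come from resampling the genes. They treat the genes as independent and hold no spread between libraries.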

Results

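Transcript counts were measured in single tdTomato-positive cells sorted from E15.5 mouse pancreata of 3 genotypes that keep or lose the Swi/Snf ATPases Brg1 and Brm in the endocrine lineage. There were 3 control, 4 Brg1Δendo;Brm+/- and 3 DKOΔendo libraries. The matrices held 8705537, 18791560 and 18586798 UMIs for control replicates 1 to 3, and 3829391, 8897670, 21456774 and 26564293 UMIs for Brg1Δendo;Brm+/- replicates 1 to 4. DKOΔendo replicates 1 to 3 held 11919609, 14940016 and 16672470 UMIs. After filtering, 1331 control, 2691 Brg1Δendo;Brm+/- and 900 DKOΔendo cells remained, with library medians between 11618 and 42285 UMIs per cell. Brg1Δendo;Brm+/- replicate 1 was the smallest library with 106 cells, of which 88 belonged to the endocrine lineage. The p-values measure only the spread between these samples, since nothing in the labels says that they came from separate animals.

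Smarca4, which encodes Brg1, was lower in both mutants in the cell classes that follow Neurog3 expression. In alpha-like cells its level was 95.3 ± 9.96 CPM in control (SD, n = 3), 16.2 ± 4.27 CPM in Brg1Δendo;Brm+/- (n = 4) and 15.9 ± 1.78 CPM in DKOΔendo (n = 3). In beta-like cells the levels were 74.9 ± 21.0, 16.6 ± 5.59 and 12.9 ± 1.57 CPM. All 4 contrasts of these classes with control were called, with log2 fold changes of -2.46 ± 0.17 (adjusted p = 1.69e-06) and -2.59 ± 0.18 (adjusted p = 2.15e-06) in alpha-like and of -2.33 ± 0.22 (adjusted p = 4.06e-05) and -2.59 ± 0.24 (adjusted p = 2.65e-05) in beta-like cells, for Brg1Δendo;Brm+/- and DKOΔendo in that order. Fev precursor-like cells kept 17.1% of the control level in Brg1Δendo;Brm+/- and 25.1% in DKOΔendo, epsilon-like cells 21.5% and 21.6%, and delta-like cells 23.6% and 9.83% (2 and 1 libraries). The shares were higher in 3 other classes: endocrine progenitor-like cells kept 41.3% of the control level in Brg1Δendo;Brm+/- and 32.9% in DKOΔendo, ductal and trunk-like cells 63.8% and 81.4%, and acinar-like cells 78.1% and 88.0%. The control itself carries 1 floxed Smarca4 allele, so these shares are not shares of a wild-type level. Smarca4 (ENSMUSG00000032187) lies on chromosome 9 of GRCm38, from 21616169 to 21704230 on the plus strand.

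**Figure D1:**
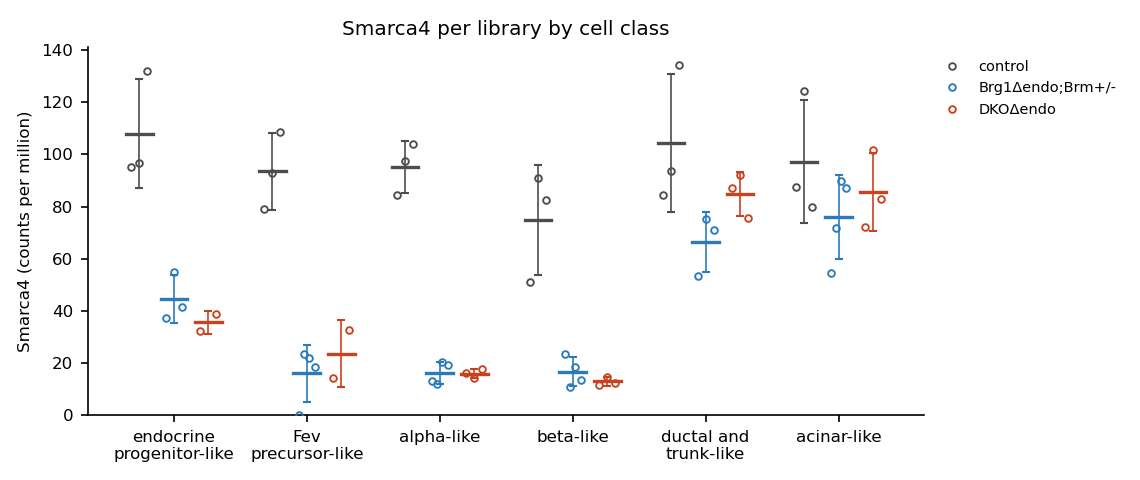
Smarca4 in CPM (vertical axis) for each cell class and genotype, with 1 point per library, the mean and its SD (error bars). In alpha-like cells every mutant library lies between 11.98 and 20.31 CPM, below every control library (84.4 to 104.0 CPM).

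Smarca2 (ENSMUSG00000024921; chromosome 19, 26605050 to 26778322, plus strand), which encodes Brm, was not called by edgeR in any contrast with control. In the endocrine lineage it measured 64.0 ± 13.7 CPM in control (n = 3), 49.5 ± 3.78 CPM in Brg1Δendo;Brm+/- (n = 4) and 43.4 ± 6.60 CPM in DKOΔendo (n = 3), with log2 fold changes of -0.35 (adjusted p = 0.984) and -0.55 (adjusted p = 0.598) against control. In 1 of 24 alternatives, limma with class as a term, chosen after the data were seen, it was called in DKOΔendo (-0.64, adjusted p = 0.00118; range 0.00118 to 1.00) and between the mutants (-0.39, adjusted p = 0.0449; range 0.0449 to 0.944). Its level in DKOΔendo was 49.9% of control in Fev precursor-like, 54.8% in alpha-like, 56.9% in beta-like and 59.7% in delta-like cells (1 DKOΔendo library). It was 70.3% in epsilon-like, 73.6% in mesenchyme-like (1 DKOΔendo library), 87.95% in endocrine progenitor-like, 89.9% in ductal and trunk-like and 95.7% in acinar-like cells. In Brg1Δendo;Brm+/-, which like control has 1 intact Brm allele, it was 71.8% in Fev precursor-like, 77.1% in alpha-like and 74.5% in beta-like cells. Delta-like cells held 78.2% there (2 libraries), and the other classes from 73.4% to 105%. Control 1 stood at 80.5 CPM in alpha-like and 83.0 CPM in beta-like cells. Control 2 stood at 48.3 and 53.2 CPM, and control 3 at 54.4 and 51.8 CPM. A limma test of class differences, chosen after the results were seen, did not call Smarca2 in DKOΔendo between alpha-like and beta-like (0.05, adjusted p = 1.00) or between acinar-like and beta-like cells (-0.73 ± 0.22, adjusted p = 0.998). It called 0 of 11773 and 0 of 11596 genes, with 434 and 579 at an unadjusted p under 0.05. On simulated data it recovered 4 of 100 genes changed 2-fold and 64 of 100 changed 4-fold, so it cannot exclude a difference between classes. Counts of 3′ tags need not show the loss of function of the Brm null allele.

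The question of which endocrine cell types form without these ATPases was addressed by the shares of cell classes. Alpha-like cells made up 29.0 ± 10.7% of endocrine lineage cells in control (n = 3), 26.6 ± 11.97% in Brg1Δendo;Brm+/- (n = 4) and 31.6 ± 1.34% in DKOΔendo (n = 3), and beta-like cells 24.9 ± 4.97%, 17.3 ± 4.76% and 23.9 ± 12.8%. Endocrine progenitor-like cells, defined by Neurog3 and its early targets, made up 11.8 ± 8.08%, 12.7 ± 6.63% and 7.71 ± 5.68%. Fev precursor-like cells, the step after Neurog3, made up 13.7 ± 4.35%, 21.2 ± 4.203% and 11.7 ± 8.05%. Epsilon-like cells, which make ghrelin, were 6.12 ± 2.29%, 9.64 ± 1.28% and 6.87 ± 4.05%. Every Brg1Δendo;Brm+/- library lay above every control library there (exact permutation p = 0.0286, unadjusted and the smallest that 4 against 3 allows). This depends on how epsilon-like cells are defined: the exact p was 0.0857 at Leiden resolution 0.6, 0.114 when clustered without marker and list genes and 0.429 with called doublets kept. With classes from the nearest control cells the direction turned (3.26 ± 1.27% in control and 2.36 ± 1.57% in Brg1Δendo;Brm+/-, exact p = 0.514). No class passed the exact 3-genotype test after adjustment over 7 classes (adjusted exact p between 0.694 and 0.879). DKOΔendo replicate 3 and the smallest library, Brg1Δendo;Brm+/- replicate 1, had only 2 and 3 endocrine progenitor-like cells.

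**Figure D2:**
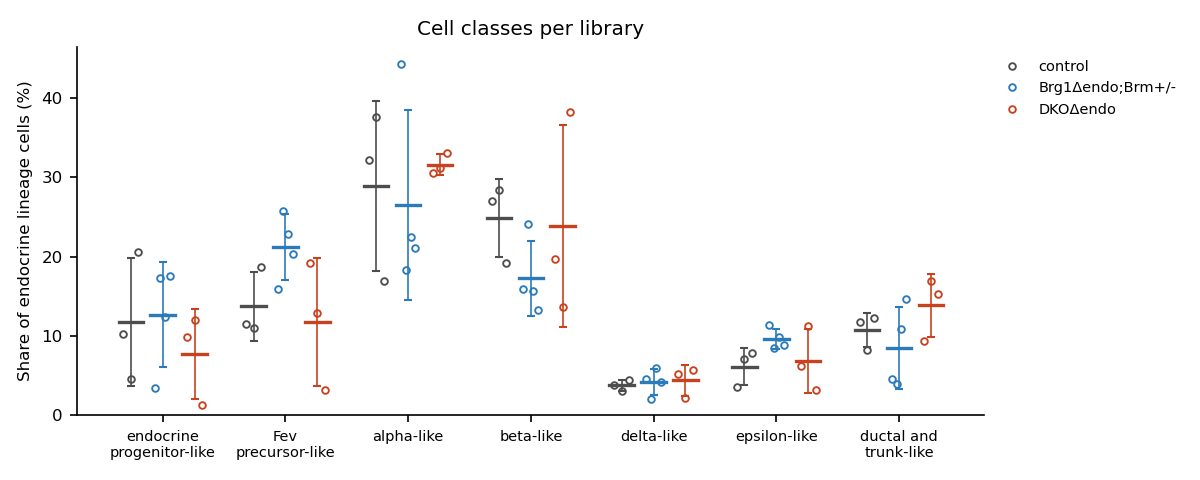
Share of endocrine lineage cells (percent, vertical axis) in each class, with 1 point per library and the mean ± SD of each genotype. The alpha-like share of Brg1Δendo;Brm+/- replicate 1 stands at 44.3%, above the other 3 libraries of its genotype (18.3 to 22.5%).

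In the endocrine lineage as a whole, Smarca4 was lower in Brg1Δendo;Brm+/- than in control, and most beta markers lay below control in a sum that also holds fewer beta-like cells. This contrast asks what loss of Brg1 does while 1 Brm allele is intact. Smarca4 fell from 91.7 ± 16.9 CPM (n = 3) to 25.7 ± 7.43 CPM (n = 4), a log2 fold change of -1.78 ± 0.21 (adjusted p = 0.0199), and was the 1 gene of 14062 called by edgeR; 594 genes had an unadjusted p under 0.05, and DESeq2 called 5. Of 12 beta markers 11 lay below 0 (median log2 fold change -0.56, camera adjusted p = 3.90e-07, and adjusted p = 0.448 with an estimated correlation). Adjusted over the list alone, 3 of them passed and 0 did over all genes tested: Npy, a peptide of fetal beta cells (98.2 ± 54.5 against 327.5 ± 55.2 CPM, log2 fold change -1.71), Slc2a2, the glucose transporter (-0.80), and the granule docking gene Sytl4 (-0.83). The beta-like share of this sum was 24.9 ± 4.97% in control and 17.3 ± 4.76% in Brg1Δendo;Brm+/- (n = 3 and 4, exact permutation p = 0.143), and within beta-like cells the median was -0.32. Of 11 islet hormones and peptides 7 lay below 0 (median -0.47, camera adjusted p = 0.0346, and adjusted p = 0.608 with an estimated correlation), and Npy alone passed when adjusted over the list alone. Of 52 G2M phase genes 47 lay below 0 (median -0.35, camera adjusted p = 8.70e-08, and adjusted p = 0.712 with an estimated correlation), 0 passed when adjusted over the list alone, and with ductal and trunk-like cells left out the median was 0.08. Further genes that the rule names were not called in the main edgeR fit: the zinc transporter Slc30a8 (-1.47, adjusted p = 0.441), and, all with an adjusted p of 0.984, Sox11 (0.54), Hes6 (0.33), Jag1 (-0.81), Rangap1 (-0.26) and Bbc3 (0.41). Among the alternatives Slc30a8 was called by DESeq2 (adjusted p = 0.000374) and by edgeR without a filter on low counts (0.00316) or without control 3 (0.0273). Limma with class as a term, chosen after the data were seen, called it too (-1.22, adjusted p = 0.00442). The other alternatives did not call it. The Smarca4 call ended without control 2 (adjusted p = 0.160), Brg1Δendo;Brm+/- 1 (0.0561), 2 (0.125) or 4 (0.0686), without both libraries deposited unfiltered (0.0730) and when all sorted cells were summed (0.449), within a range over 24 alternatives of 2.72e-14 to 0.449. The log2 fold change stayed between -1.90 and -1.68 in these fits, and was -1.45 with all sorted cells.

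In the DKOΔendo lineage most beta markers and islet hormones lay below control, while edgeR called 0 of 14062 genes. This contrast asks what losing both ATPases does. Smarca4 measured 28.8 ± 7.05 CPM (n = 3) against 91.7 ± 16.9 CPM (n = 3), with a log2 fold change of -1.67 ± 0.23 (adjusted p = 0.0916), and 808 genes had an unadjusted p under 0.05. DESeq2 called 31 genes. Ductal and trunk-like cells, which keep Smarca4, are part of this sum: in islet classes without them, an alternative chosen after the data were seen, Smarca4 was called (-2.43, adjusted p = 0.000181; range over 24 alternatives 3.01e-14 to 0.586). Of 12 beta markers 11 lay below 0 (median -0.46, camera adjusted p = 1.64e-06, and adjusted p = 0.574 with an estimated correlation); adjusted over the list alone, 2 passed, Npy (-1.99; 82.4 ± 37.8 against 327.5 ± 55.2 CPM) and the motor neuron and beta cell transcription factor gene Mnx1 (-0.60; 26.5 ± 0.925 against 40.0 ± 6.88 CPM). Of 11 islet hormones and peptides 10 lay below 0 (median -0.58, camera adjusted p = 0.000124, and adjusted p = 0.399 with an estimated correlation), with Npy alone passing when adjusted over the list alone. Of 9 alpha markers 9 lay below 0 (median -0.27, camera adjusted p = 0.0171, and adjusted p = 0.805 with an estimated correlation) and 0 passed when adjusted over the list alone. Of 52 G2M phase genes 47 lay below 0 (median -0.23, camera adjusted p = 0.0171, and adjusted p = 0.805 with an estimated correlation), 0 passed when adjusted over the list alone, and the median was -0.02 with equal cell numbers per library, 0.04 without control 2 and 0.05 without ductal and trunk-like cells. Also not called in the main edgeR fit were Slc30a8 (-1.28, adjusted p = 0.298), Slc2a2 (-0.59, adjusted p = 0.841) and Mfng (-0.48, adjusted p = 0.857). The same held for Nrarp (-0.91, adjusted p = 0.841), Hmgb2 (-0.28, adjusted p = 0.910) and Sesn2 (0.57, adjusted p = 0.409). Of 24 alternatives, 3 called Slc30a8: DESeq2, edgeR without a filter on low counts and limma with class as a term. The limma fit was chosen after the data were seen (-1.51, adjusted p = 0.000252). Over the 24 alternatives the log2 fold change of Slc30a8 ran from -1.56 to -1.05 and its adjusted p from 0.000252 to 0.9035.

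Compared directly, the lineage cells of DKOΔendo and Brg1Δendo;Brm+/- differed by 0 called genes of 14062 in edgeR, with 1113 genes at an unadjusted p under 0.05 and 0 called by DESeq2. This contrast asks what the remaining Brm allele does once Brg1 is lost. Smarca4 differed by 0.11 (adjusted p = 0.912) and Smarca2 by -0.20 (adjusted p = 0.699). Of 81 genes of cytosolic ribosomal proteins 74 lay below 0 (median -0.30, camera adjusted p = 1.11e-18, and adjusted p = 0.401 with an estimated correlation), and 0 passed when adjusted over the list alone. In acinar-like cells of the same libraries the median was 147% of this. The rule's other genes were not called in the main edgeR fit: Mnx1 (-0.44), Cck (-1.03), Ptprn (0.39), Cacna1a (-0.42), Ppp1r14a (-1.09), Mfng (-0.65) and Bax (-0.53), each with an adjusted p of 0.612, and Ncapd2 (0.41, adjusted p = 0.630). Of these, Bax was called by limma with class as a term, chosen after the data were seen (-0.38, adjusted p = 0.00112).

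In endocrine progenitor-like cells of Brg1Δendo;Brm+/-, progenitor markers lay above and alpha markers below those of control, by amounts that depend on how the class is drawn. All 13 endocrine progenitor markers lay above 0 (median 0.48, camera adjusted p = 3.63e-09, and adjusted p = 0.220 with an estimated correlation) and all 9 alpha markers below 0 (median -0.81, camera adjusted p = 3.63e-09, and adjusted p = 0.220 with an estimated correlation). Adjusted over the list alone, 4 progenitor markers passed, among them Gadd45a (565.5 ± 155.0 against 357.5 ± 99.7 CPM, n = 3 each, log2 fold change 0.65) and Numbl (0.48), with Cbfa2t3 (0.56) and Smarcd2 (0.46), and 2 alpha markers, Irx2 (-1.27) and Cltrn (-1.004). Over all 10204 genes edgeR called 0, with 442 at an unadjusted p under 0.05, and DESeq2 called 1. Both lists define classes. The medians were 0.26 and -0.42 when cells were clustered without marker and list genes. They were 0.09 (camera adjusted p = 0.461) and -0.23 (camera adjusted p = 0.646) when classes came from the nearest control cells, which ended both calls. That smaller class held 10, 7 and 38 cells in controls 1 to 3, so its fit set 3 libraries against 2. The class holds 2 clusters, and the one with more progenitor markers made up 56.6, 77.0 and 50.4% of it in the 3 Brg1Δendo;Brm+/- libraries used, against 40.0, 60.0 and 43.5% in control. Within each cluster, in fits chosen after the data were seen with 3 libraries against 2, the progenitor medians were 0.12 and 0.19 and the alpha medians -0.05 (5 genes) and -0.55 (9 genes). Smarca4 measured 44.6 ± 9.32 against 108 ± 20.9 CPM (-1.31, adjusted p = 0.0781). In DKOΔendo, where 2 libraries had at least 10 such cells, edgeR called 0 genes, with 354 at an unadjusted p under 0.05 and 1 called by DESeq2; Smarca4 measured 35.6 ± 4.42 CPM (n = 2, log2 fold change -1.63, adjusted p = 0.0844).

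In Fev precursor-like cells Smarca4 fell in Brg1Δendo;Brm+/-, from 93.5 ± 14.8 CPM (n = 3) to 16.0 ± 10.9 CPM (n = 4, log2 fold change -2.28 ± 0.26, adjusted p = 0.000567). It was the 1 gene of 9061 called, with 275 at an unadjusted p under 0.05 and 1 called by DESeq2. Brg1Δendo;Brm+/- replicate 1 had 0 Smarca4 UMIs there, which allows up to 13.2 CPM, and the call ended without control 3 (adjusted p = 0.0591; range over 18 alternatives 2.48e-22 to 0.0591). In DKOΔendo 9 of 10 islet hormones and peptides lay below 0 (median -1.60, camera adjusted p = 1.16e-06, and adjusted p = 0.0383 with an estimated correlation). Adjusted over the list alone, 3 passed: Pyy (1214 ± 223 CPM, n = 2, against 3399 ± 1810 CPM, n = 3, log2 fold change -1.48), Ppy (-2.15) and Gast (-1.78), while Sst lay above 0 (2.73, not passing). Clustered without marker and list genes, the median was -0.79 and the call ended (adjusted p = 0.232, and adjusted p = 0.836 with an estimated correlation). Over all genes edgeR called 0, with 411 at an unadjusted p under 0.05 and 4 called by DESeq2; Smarca4 measured 23.5 ± 12.8 CPM (n = 2, log2 fold change -2.09, adjusted p = 0.0602).

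In alpha-like cells of DKOΔendo, alpha markers lay below control, and Slc30a8, the zinc transporter of secretory granules, fell from 140.9 ± 48.0 CPM (n = 3) to 29.9 ± 18.4 CPM (n = 3, log2 fold change -2.21 ± 0.35, adjusted p = 0.0408). All 9 alpha markers lay below 0 (median -0.55, camera adjusted p = 4.82e-07, and adjusted p = 0.0326 with an estimated correlation). Adjusted over the list alone, 4 fell and 0 passed over all genes: Gcg, which encodes glucagon (14150 ± 8765 against 48230 ± 25100 CPM, log2 fold change -1.77), the transcription factor gene Irx2 (-0.76), Ttr (-0.67) and Slc38a5 (-0.62). The delta markers went the other way in 4 of 5 (median 2.11, camera adjusted p = 0.000116, and adjusted p = 0.229 with an estimated correlation). Of these Sst, which encodes somatostatin (741.9 ± 768.7 against 49.5 ± 75.5 CPM, log2 fold change 3.92), the delta cell transcription factor gene Hhex (19.2 ± 0.898 against 4.09 ± 4.26 CPM, log2 fold change 2.70) and Frzb (2.11) passed when adjusted over the list alone. Clustered without marker and list genes, the medians were -0.60 (adjusted p = 0.0214 with an estimated correlation) and 2.77. The class holds 3 clusters, with 8 alpha markers up in the one led by Gcg and 4 and 5 in the others. Both others have Ppy among their top 10 genes. Clustered without marker and list genes, a cluster of 341 cells with Gip, Ppy and Pyy among its top 10 genes stayed unnamed. The cluster led by Gcg made up 54.1 ± 18.9% of alpha-like cells in control and 39.4 ± 4.32% in DKOΔendo (n = 3 each), and another held 26 of the 52 of DKOΔendo 3. Within clusters, in fits chosen after the data were seen, the alpha median was -0.34 in the one led by Gcg (3 libraries against 3) and -0.33 in a second (2 against 3), with 9 of 9 markers below 0 in each. The delta markers lay below 0 in the first (2 of 2 tested) and above in the second (3 of 4, median 2.35). The third cluster had too few libraries. Over all 11591 genes edgeR called 3 lower and 0 higher in DKOΔendo (990 at an unadjusted p under 0.05; DESeq2 called 41): Smarca4, Slc30a8 and, named after its values were seen, 5330439M10Rik (1.89 ± 1.09 against 37.5 ± 31.3 CPM). The Slc30a8 call held in 11 of 19 alternatives (adjusted p from 3.97e-31 to 0.152) and ended without control 1 (0.106), control 2 (0.152), Brg1Δendo;Brm+/- 1 (0.0632), 3 (0.0690) or 4 (0.0708), or DKOΔendo 2 (0.0762). It also ended without both libraries deposited unfiltered (0.146) and at Leiden resolution 0.6 (0.0732). The log2 fold change stayed between -2.60 and -1.80 in all 19. The alpha list held with an estimated correlation in 1 of 10 fits that leave out a library (adjusted p = 0.0156 without control 3, up to 0.133 without DKOΔendo 2). In Brg1Δendo;Brm+/- Smarca4 was the 1 gene called, with 740 at an unadjusted p under 0.05 and 3 called by DESeq2. Slc30a8 measured 42.0 ± 4.17 CPM there (n = 4, log2 fold change -1.75, adjusted p = 0.167) and was not called.

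**Figure D3:**
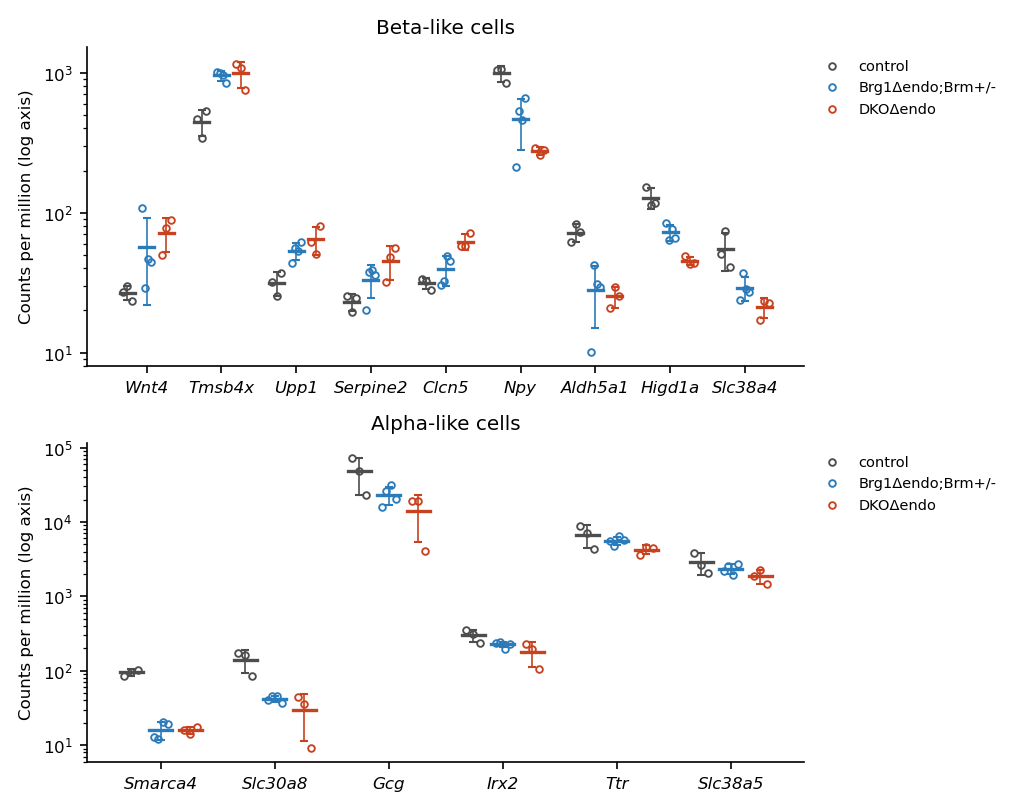
Levels in CPM (log scale, vertical axis) of genes in alpha-like and beta-like cells, with 1 point per library and the mean ± SD of each genotype. Npy in beta-like cells averages 988.6 CPM in control, 465.0 CPM in Brg1Δendo;Brm+/- and 276.2 CPM in DKOΔendo.

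Beta-like cells of DKOΔendo showed the largest number of genes called against control in the main edgeR fits of the lineage and 4 classes, 26 higher and 19 lower of 10919 in edgeR, with 912 at an unadjusted p under 0.05 and 47 called by DESeq2. Npy fell from 988.6 ± 125 to 276.2 ± 17.2 CPM (n = 3 each, log2 fold change -1.84 ± 0.27, adjusted p = 0.00440). Lower too were Higd1a, a mitochondrial gene induced by hypoxia (45.2 ± 3.21 against 127.5 ± 21.7 CPM, log2 fold change -1.49 ± 0.16, adjusted p = 0.000212), Aldh5a1, a dehydrogenase of GABA breakdown (25.2 ± 4.26 against 72.1 ± 10.5 CPM, log2 fold change -1.54 ± 0.21, adjusted p = 0.00335), and the amino acid transporter Slc38a4 (21.1 ± 3.51 against 55.0 ± 16.8 CPM, log2 fold change -1.38 ± 0.22, adjusted p = 0.00618). Among the genes that rose, Wnt4 encodes a secreted Wnt ligand (72.0 ± 19.6 against 26.8 ± 3.12 CPM, log2 fold change 1.45 ± 0.28, adjusted p = 0.0262) and Tmsb4x an actin-binding thymosin (989.6 ± 212 against 447 ± 97.0 CPM, log2 fold change 1.15 ± 0.20, adjusted p = 0.0134). Upp1, a uridine phosphorylase (1.07 ± 0.19, adjusted p = 0.0150), Clcn5, an endosomal chloride transporter (1.01 ± 0.18, adjusted p = 0.0134), and the protease inhibitor gene Serpine2 (1.04 ± 0.21, adjusted p = 0.0360) rose as well. All 12 beta markers lay below 0 (median -0.56, camera adjusted p = 6.10e-09, and adjusted p = 0.0386 with an estimated correlation). Adjusted over the list alone, 5 fell, of which Npy alone was called over all genes: Npy, Ins1, an insulin gene (18670 ± 9064 against 37790 ± 8516 CPM, log2 fold change -1.02), the glucose transporter gene Slc2a2 (-0.68), and Mnx1 (-0.82) and Nkx6-1 (-0.49), which encode beta cell transcription factors. Ins2 did not pass (-0.64, adjusted p = 0.578). Of 11 islet hormones and peptides 8 lay below 0 (median -0.64, camera adjusted p = 0.000453, and adjusted p = 0.379 with an estimated correlation), with Npy and Ins1 passing when adjusted over the list alone. Clustered without marker and list genes, the beta list had a median of -0.45 (camera adjusted p = 4.09e-05, and adjusted p = 0.151 with an estimated correlation), and 39 genes were called, 29 of them among the 45.

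Of the genes named here, Smarca4, Npy, Aldh5a1 and Higd1a stayed past the threshold in beta-like cells of DKOΔendo in all 19 alternatives. The count of called genes fell to 9 without control 2, 19 without control 3, 27 without DKOΔendo 1 and 18 without DKOΔendo 3. Wnt4 lost its call without control 1 (adjusted p = 0.0549), 2 (0.115) or 3 (0.150) and without DKOΔendo 2 (0.0588) or 3 (0.218). It also lost it with a replicate block (0.0563) and with classes from the nearest control cells (0.127). Serpine2 lost it without control 1 (0.0549), 2 (0.247) or 3 (0.116), Brg1Δendo;Brm+/- 4 (0.0530), DKOΔendo 2 (0.0836) or 3 (0.336). It also lost it with a sex term (0.0605) and in all 3 other clusterings (0.0727 to 0.109). Clcn5 lost it without control 2 (0.0702) or 3 (0.1003) or DKOΔendo 3 (0.134). Upp1 lost it without control 2 (0.150) or DKOΔendo 3 (0.155), Tmsb4x without control 2 (0.112) or DKOΔendo 1 (0.0624), and Slc38a4 without control 2 (0.0616) or with classes from the nearest control cells (0.0717). The direction of each held in all 19 alternatives, with log2 fold changes from 1.25 to 1.96 for Wnt4, 0.82 to 1.23 for Serpine2, 0.88 to 1.15 for Clcn5, 0.85 to 1.40 for Upp1, 0.98 to 1.31 for Tmsb4x and -1.57 to -1.07 for Slc38a4. Without a filter on low counts 259 genes were called in beta-like and 301 in alpha-like cells of DKOΔendo, so the rank of the 2 classes turned there. Over the 19 alternatives the adjusted p ran from 9.63e-11 to 0.218 for Wnt4, 0.000117 to 0.336 for Serpine2 and 4.92e-05 to 0.134 for Clcn5. It ran from 8.54e-06 to 0.155 for Upp1, 2.10e-06 to 0.112 for Tmsb4x and 6.50e-09 to 0.0717 for Slc38a4.

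In beta-like cells of Brg1Δendo;Brm+/- edgeR called 1 higher and 2 lower genes, with 673 at an unadjusted p under 0.05 and 10 called by DESeq2. Cda, which encodes cytidine deaminase, rose from 98.1 ± 10.3 CPM (n = 3) to 193.9 ± 29.3 CPM (n = 4, log2 fold change 0.96 ± 0.15, adjusted p = 0.0358), Aldh5a1 fell from 72.1 ± 10.5 to 28.1 ± 13.2 CPM (-1.21 ± 0.20, adjusted p = 0.0376), and Smarca4 fell. Of 12 beta markers 10 lay below 0 (median -0.32, camera adjusted p = 0.00245, and adjusted p = 0.273 with an estimated correlation); adjusted over the list alone, Npy alone fell (465.0 ± 186 against 988.6 ± 125 CPM, log2 fold change -1.06). The median was -0.39 when cells were clustered without marker and list genes. Cda held in 10 of 19 alternatives (adjusted p from 1.95e-05 to 0.298) and ended without control 2 (adjusted p = 0.298) or 3 (0.111), Brg1Δendo;Brm+/- 2 (0.0521) or 3 (0.143), and DKOΔendo 1 (0.0530) or 3 (0.0518). It also ended in all 3 other clusterings (0.0816 to 0.186), and its log2 fold change stayed between 0.84 and 1.03 throughout. Aldh5a1 held in 12 (5.49e-08 to 0.300) and ended without control 2 (0.300) or 3 (0.111), Brg1Δendo;Brm+/- 3 (0.143) or 4 (0.196), and DKOΔendo 1 (0.0530) or 3 (0.0623). It also ended with classes from the nearest control cells (0.0590), and its log2 fold change stayed between -1.37 and -1.10 throughout.

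The 45 genes called in beta-like cells of DKOΔendo moved the same way in Brg1Δendo;Brm+/-, most of them by less. Cda and Wif1, at 0.96 and 2.71 against 0.79 and 2.59, moved by more. All 45 had the same sign there, 40 had an unadjusted p under 0.05, and the median share of the DKOΔendo change was 63.7%. Both contrasts use the same 3 control libraries, which alone makes changes look shared. Over all 10919 genes 61.1% had the same sign, against 67.1% in simulated unchanged groups with shared controls. The correlation of the log2 fold changes was 0.545, against 0.503 ± 0.0166 (SD over 20 simulations). The 45 genes were selected on DKOΔendo, which alone makes its changes look larger. In 20 simulations these 45 genes were given their estimated change in DKOΔendo only. Of those called, at most 73.5% had the same sign, and the median share was at most 8.20%. The simulations took the 45 genes as given and did not select them from all genes tested. They therefore cannot show how much of the shared direction comes from that selection through the shared controls. Called in both contrasts were Cda, Smarca4 and Aldh5a1, of which Smarca4 is the gene targeted in both mutants. Independent calls would share 0.00238 higher and 0.00348 lower genes, but contrasts with shared controls are not independent. Simulated unchanged groups with shared controls shared 0.05 genes, but hold no changed genes. Neither value therefore measures the overlap to expect for this many calls. Between both mutants directly, edgeR called 0 of 10919 genes in beta-like cells, with 1143 at an unadjusted p under 0.05. DESeq2 called 125 there, and edgeR without DKOΔendo 1 called 2. The tools disagree, and on simulated lineage data the false share of DESeq2 calls exceeded its threshold. The contrast also largely follows the line in mitochondrial share that is given with the other splits. A difference between the mutants in beta-like cells therefore stays open.

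**Figure D4:**
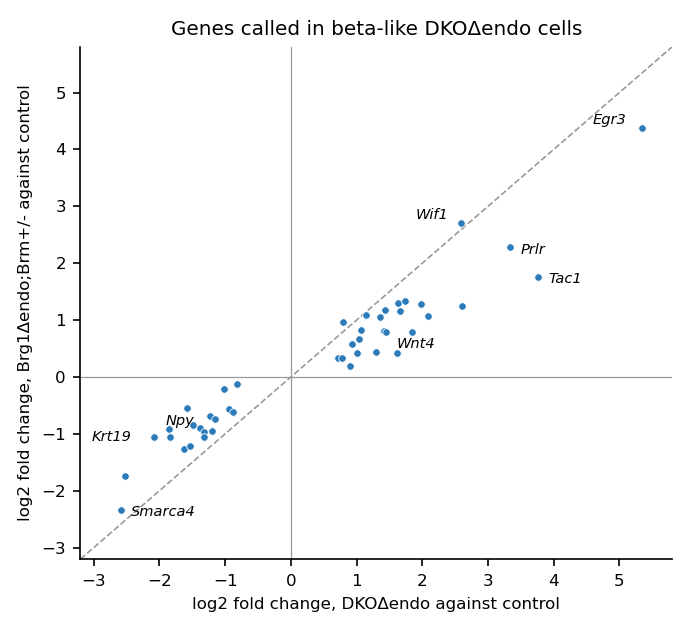
Log2 fold change against control in beta-like cells of Brg1Δendo;Brm+/- (vertical axis) and of DKOΔendo (horizontal axis) for the 45 genes called in DKOΔendo, 1 point per gene; the dashed line marks equal changes. All 45 points share their sign in both mutants, with a median share of 63.7% of the DKOΔendo change.

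Proliferation was read from cells with a UMI of Mki67 or Top2a after each cell was thinned to 3000 UMIs, since the series title names endocrine cell expansion. The share was 5.39 ± 0.413% in control (n = 3), 3.75 ± 2.08% in Brg1Δendo;Brm+/- (n = 4) and 6.71 ± 1.67% in DKOΔendo (n = 3), with an exact permutation p of 0.129 over the 3 genotypes. Without Brg1Δendo;Brm+/- 4 the exact p was 0.00714 with a mean of 2.84 ± 1.25% in that genotype. This is the smallest of the unadjusted exact p-values found when each library was left out in turn. Ductal and trunk-like cells, which hold most such cells, made up 10.8 ± 2.18%, 8.49 ± 5.16% and 13.9 ± 4.01% of lineage cells (n = 3, 4 and 3), and 14.7% in Brg1Δendo;Brm+/- 4 against 3.92 to 10.8% in the other 3 libraries of that genotype. Such cells were 34.5% of ductal and trunk-like cells (median 28450 UMIs per cell before thinning) but 0.955% of alpha-like (21400 UMIs) and 0.761% of beta-like cells (23550 UMIs), pooled over genotypes. How much of these low shares comes from free RNA was not measured. The proliferating share was not tested without ductal and trunk-like cells. It therefore cannot tell their number from proliferation in the islet classes.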

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

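Chosen only after the results were seen were both tests of DKOΔendo replicate 3, the limma test of class differences, the sex term test of the beta-like genes, the exact tests of the Smarca4 ratio between classes and, among the alternatives, the fit with class as a term and the sex term.

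The alpha-like share of Brg1Δendo;Brm+/- replicate 1 was 44.32% of endocrine lineage cells (39 of 88 cells; exact 95% interval 33.7 to 55.3%), far from the other 3 libraries of its genotype, which lay between 18.3% and 22.5%. Nrarp, a Notch target, measured 7.321 CPM in the endocrine lineage of the same library, against 2.13 to 2.58 CPM in the other 3. It is the smallest library, with 3829391 UMIs and 106 cells, and 1 of the 2 deposited unfiltered. A gap of this size is found by chance in about 1 in 20 groups of values, and 37 values were examined, of which 2 had such a gap. No explanation was tested for either value.

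The loss of Smarca4 differed between cell classes. The log2 ratio of Smarca4 in beta-like over acinar-like cells was -0.39 ± 0.41 in control (n = 3), -2.15 ± 0.67 in Brg1Δendo;Brm+/- (n = 4) and -2.63 ± 0.09 in DKOΔendo (n = 3), and differed between genotypes (exact permutation p = 0.00905 over 4200 regroupings). Over ductal and trunk-like cells the ratios were -0.49 ± 0.39 (n = 3), -2.15 ± 0.17 (n = 3) and -2.63 ± 0.15 (n = 3), with an exact permutation p of 0.00357 over 1680 regroupings. Each of the 7 mutant libraries lay below each control library in the acinar comparison. A limma test of class differences over 11596 genes was run first and called 0 genes (553 and 579 at an unadjusted p under 0.05 in the 2 mutants), with Smarca4 at adjusted p = 0.962 and 0.393; on simulated data it recovered 4 of 100 genes changed 2-fold and 64 of 100 changed 4-fold. The single-gene test was added after that.

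Acinar-like cells are present in all 10 sorted libraries although the sort selected cells with a history of Neurog3-Cre activity. Cells carried through the sort without recombination would keep the control level of Smarca4. The group means of acinar-like cells were 78.1% of control in Brg1Δendo;Brm+/- and 88.0% in DKOΔendo. These lie nearer to that level than the 16.97% and 16.7% of alpha-like cells. The lowest mutant library, Brg1Δendo;Brm+/- 1, stood at 54.7 CPM. A wide spread (97.3 ± 23.7, 75.9 ± 16.2 and 85.6 ± 14.99 CPM) leaves room for a small recombined part. A late reporter recombination without loss of both Smarca4 alleles was not tested and stays open.

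The 45 genes called in beta-like cells of DKOΔendo could come from a changed mix of the 2 beta-like clusters, from free RNA, from the sex of the libraries, or from a response of beta-like cells to the genotype. Within the clusters the genes kept a median of 110% (103 to 118%) and 81.9% (78.9 to 89.4%) of their class-wide change, which argues against a shift between clusters as the whole cause; cluster 1 made up 42.0 ± 4.19%, 36.4 ± 7.12% and 51.3 ± 18.9% of beta-like cells in control, Brg1Δendo;Brm+/- and DKOΔendo (exact permutation p = 0.261). In acinar-like cells the same genes moved by a median of 20.9% (14.0 to 28.8%) of the beta-like change, with 34 of 45 in the same direction. Acinar-like cells were deeper, with a median of 49868 UMIs against 36947 and 18451 in the 2 beta-like clusters, so free RNA would weigh less in them. This test therefore cannot tell how much of the change came from free RNA shared by all cells of a library. With 3 against 3 libraries the 10 possible splits are too few for a share under 0.05; the real split called 45 genes and the highest of the others 1. With a sex term the 45 genes kept a median of 100% (93.8 to 103%) of their change and 48 genes were called, 32 of them among the 45, which argues against sex as the whole cause. A response to the genotype stays open as a hypothesis, beside free RNA. The count was 9 without control 2, 19 without control 3, 27 without DKOΔendo 1 and 18 without DKOΔendo 3, each a fit with 2 libraries in 1 arm.

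DKOΔendo replicate 3 stands apart in composition, with 157 of 270 cells in the endocrine lineage, 74 mesenchyme-like cells and 2 endocrine progenitor-like cells. A swap with a control library is argued against by Smarca4 in its lineage cells, 27.05 CPM against at least 74.4 CPM in the controls. Cells with UMIs of at least 4 of 7 adrenal cortex genes, a signal outside the report's comparisons, were 0.885% of its cells outside the lineage (1 of 113; exact 95% interval 0.0224 to 4.83%) and 0 of 638 in the other libraries, which allows up to 0.470%. Inside its endocrine lineage 1 of 157 cells (0.637%) had them as well. The 2 parts are unlike: its cells outside the lineage held 574 Cyp21a1, 364 Hsd3b1 and 341 Cyp11b1 UMIs, its lineage cells 7, 1 and 1. Fdx1, also among the 7 genes, had UMIs in every library. Adrenal cortex transcripts were thus present outside the lineage. With 1 cell in each part the extent of a carry-over stays open, but such cells are too few to make up the library's composition. Dissection, sorting and a biological difference between embryos were not tested and stay open.

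Other splits of the same libraries were counted for each fit across genes. For Brg1Δendo;Brm+/- against control, 4 of 35 splits of the endocrine lineage gave as many genes as the real 1 (highest other 29), 5 of 35 in Fev precursor-like (real 1, highest other 9), 7 of 35 in alpha-like (real 1, highest other 14) and 3 of 35 in beta-like cells (real 3, highest other 7), so chance cannot be excluded for these counts. For DKOΔendo against Brg1Δendo;Brm+/- in the lineage, the real count was 0 (highest other 3), so that 35 of 35 splits reach it by construction and this count tests nothing. A split that calls 29 genes where the real one calls 1 points to a structure of the samples other than genotype. Splits were too few for a share under 0.05 for DKOΔendo against control in the lineage (10 of 10; real 0, highest other 0) and alpha-like cells (2 of 10; real 3, highest other 3), and for the 3 against 3 libraries of endocrine progenitor-like cells (10 of 10; real 0, highest other 1), where each real 0 is again reached by construction; in beta-like cells DKOΔendo gave 1 of 10. With class as a term, 14 of 35 splits reached the real 138 genes of Brg1Δendo;Brm+/- against control (highest other 1372). Between the mutants 3 of 35 reached the real 648 (highest other 1186), again pointing to a structure of the samples. For DKOΔendo against control 1 of 10 reached the real 407 (highest other 178), where splits are too few. The split with 1372 genes set Brg1Δendo;Brm+/- 1, 2 and 3 with control 1 against the rest. That with 1186 set Brg1Δendo;Brm+/- 1, 2 and 3 against Brg1Δendo;Brm+/- 4 and all DKOΔendo libraries. Control 1 and Brg1Δendo;Brm+/- 1, 2 and 3 had median mitochondrial shares of 2.45 to 3.36%, the other libraries 3.90 to 5.18%. The contrast between the mutants largely follows this line and cannot be told apart from it. For the number of lists called, 13 of 35 splits reached the real 8 for Brg1Δendo;Brm+/- against control in the lineage (highest other 15). In the same contrast 34 of 35 reached the real 1 in Fev precursor-like cells (highest other 8). In alpha-like cells 35 of 35 reached the real 1 (highest other 9), and in beta-like cells 14 of 35 the real 5 (highest other 8). Between the mutants 34 of 35 reached the real 5 in the lineage (highest other 14). Chance cannot be excluded for these counts. In progenitor-like cells of Brg1Δendo;Brm+/- 1 of 10 reached the real 11 (median of the others 7, highest 10), where splits are too few. For DKOΔendo against control 5 of 10 reached the real 9 in the lineage (highest other 14), 5 of 10 the real 5 in alpha-like (highest other 8) and 7 of 10 the real 3 in beta-like cells (highest other 9), where splits are too few.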

How the results depend on the processing

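Chosen only after the data were seen were the islet classes without ductal and trunk-like cells, the sex term, the fit with class as a term, and the alternatives of the 3 list tests with an estimated correlation; the other alternatives were planned. Of the planned values for the main results, 252 stayed on their side of the threshold or within 1.5 times the count, 65 were higher or gained a call, and 23 were lower or lost it; of the added ones the counts were 13, 8 and 2. For the genes and lists named, 1325 planned values kept direction and side, 75 gained and 114 lost a call and 4 reversed, and 136, 11, 32 and 6 of the added ones. Of 80 list results the text names 16, chosen after the alternatives were seen; the 64 left out hold 22 reversed and 271 weaker values of 1215. The cause of each change below was not tested unless it is stated.

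Smarca4 kept its call in both mutants and both alpha-like and beta-like cells in all 19 alternatives of each. No class share passed the threshold in any alternative run. Gene counts are given for Brg1Δendo;Brm+/- against control and then DKOΔendo against control. Without a filter on low counts they were 4 and 14 in the lineage, 67 and 55 in endocrine progenitor-like, 37 and 62 in Fev precursor-like, 117 and 301 in alpha-like and 119 and 259 in beta-like cells. By DESeq2 they were 5 and 31, 1 and 1, and 3 and 41 in lineage, progenitor-like and alpha-like cells, 4 in Fev precursor-like DKOΔendo and 10 in beta-like Brg1Δendo;Brm+/- cells. Between the mutants in beta-like cells, where the main fit called 0, DESeq2 called 125 genes, a fit without a filter on low counts 129, clustering without marker and list genes 1 and leaving out DKOΔendo 1 gave 2. With a replicate block they were 2 in the DKOΔendo lineage, 17 and 11 in progenitor-like, 4 and 8 in Fev precursor-like and 10 in alpha-like DKOΔendo cells, and the block gave 9 called lists between the mutants; the replicate numbers do not pair the libraries, so the block has no known meaning. With the sex term they were 2 in the DKOΔendo lineage, 3 and 24 in alpha-like and 7 in beta-like Brg1Δendo;Brm+/- cells, with 5 lists called in the DKOΔendo lineage.

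Without both libraries deposited unfiltered the count was 0 and 4 lists were called in the Brg1Δendo;Brm+/- lineage, and 5 genes in Fev precursor-like DKOΔendo cells. With all sorted cells the Brg1Δendo;Brm+/- count was 0. In the DKOΔendo lineage 1 gene was called with the stricter cell filter, with equal cell numbers and in islet classes only, where 4 lists were called. With class as a term 138, 407 and, between the mutants, 648 genes were called. With an estimated correlation 0 lists were called in each of the 3 lineage contrasts; between the mutants 8 lists were called with the stricter filter and 11 in progenitor-like cells only. Clustering without marker and list genes gave 3 genes in progenitor-like and 5 in beta-like Brg1Δendo;Brm+/- cells and 18 in alpha-like DKOΔendo cells. Classes from the nearest control cells gave 2 genes each in progenitor-like, Fev precursor-like and alpha-like Brg1Δendo;Brm+/- cells. They gave 23 in beta-like DKOΔendo cells, 20 of them among the 45. Of progenitor-like cells drawn this way control 2 held 7 and was left out. DKOΔendo 1 to 3 held 9, 13 and 0, so only replicate 2 entered and no count is given. Leiden resolution 0.6 gave 1 gene in progenitor-like and 2 in Fev precursor-like DKOΔendo cells. The proliferating share unthinned had an exact permutation p of 0.0233 (14.8 ± 1.96, 10.1 ± 3.76 and 19.5 ± 2.28%); deeper cells show more UMIs, which thinning removes.

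Leaving out each library gave 0 to 5 genes in the Brg1Δendo;Brm+/- lineage (0 without control 2 and without Brg1Δendo;Brm+/- 1, 2 or 4; 5 without control 3) and 0 to 1 in the DKOΔendo lineage (1 without control 3). The ranges were 0 to 1 and 0 to 8 in progenitor-like (1 and 8 without Brg1Δendo;Brm+/- 3), 0 to 1 and 0 to 13 in Fev precursor-like (0 without control 3; 5 and 13 without Brg1Δendo;Brm+/- 1 and 3), and 1 to 4 and 2 to 12 in alpha-like cells (12 without control 3). In beta-like cells they were 1 to 5 and 9 to 57 (9 without control 2, 57 without Brg1Δendo;Brm+/- 1). Lists called ranged from 4 (without control 1) to 13 (without Brg1Δendo;Brm+/- 1) for Brg1Δendo;Brm+/-, from 5 (without DKOΔendo 3) to 14 (without DKOΔendo 2) for DKOΔendo and from 4 to 10 (without DKOΔendo 1) between the mutants, and the exact p of the proliferating share from 0.00714 (without Brg1Δendo;Brm+/- 4) to 0.248 (without DKOΔendo 2).

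Reversed were Nrarp in the DKOΔendo lineage (0.30 in islet classes only, 0.20 with class as a term) and Smarca4 between the mutants (-0.30 in islet classes only, -0.28 with class as a term, and from -0.10 without DKOΔendo 2 to 0.25 without DKOΔendo 1). The G2M phase median of Brg1Δendo;Brm+/- was 0.16 with equal cell numbers and 0.078 in islet classes only. That of DKOΔendo was -0.019 with equal cell numbers (where the camera direction turned), 0.052 in islet classes only, and ran from -0.49 without DKOΔendo 2 to 0.040 without control 2. The beta list of DKOΔendo beta-like cells lost its call with an estimated correlation in all 3 other clusterings (adjusted p = 0.151, 0.171 and 0.184) and kept it in 2 of 10 fits that leave out a library (0.0283 to 0.221). The Fev precursor-like hormone list lost it in all 3 (0.836, 0.0789 and 0.699) and kept it in 3 of 9 (0.0355 to 0.217). Of these 9, the fits without DKOΔendo 1 (0.155) and 2 (0.217) hold 1 DKOΔendo library, which is assumed to vary like the other groups, as in the gene counts of progenitor-like and Fev precursor-like cells without either; the other 7 gave 0.0355 to 0.129. The alpha list kept it in all 3 (0.0214, 0.0496 and 0.0128). Depth limits the smallest library, Brg1Δendo;Brm+/- 1, and the progenitor-like and Fev precursor-like sums of DKOΔendo, which rest on 2 libraries.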

Other observations

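Chosen only after the results were seen were the genes named in the first 2 paragraphs and the fit with class as a term; both tests of the ribosomal protein genes were planned.

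Among the genes called in beta-like cells of DKOΔendo are lowly expressed ones that the naming rule left out for their level, named here after their values were seen. Tac1, a tachykinin gene of enteroendocrine cells, measured 30.1 ± 23.5 CPM in DKOΔendo (n = 3), 8.83 ± 3.53 CPM in Brg1Δendo;Brm+/- (n = 4) and 2.49 ± 1.73 CPM in control (n = 3). The prolactin receptor gene Prlr measured 14.7 ± 8.89, 9.03 ± 6.30 and 1.34 ± 0.501 CPM, and Cpb2, a carboxypeptidase gene, 24.0 ± 11.99, 9.76 ± 1.74 and 4.24 ± 0.483 CPM. The duct keratin gene Krt19 went the other way, with 7.43 ± 1.51, 13.2 ± 7.71 and 31.3 ± 11.6 CPM. Of 19 alternatives, the call of Cpb2 held in 19, that of Krt19 in 18, that of Tac1 in 16 and that of Prlr in 14, each with the same sign in all 19. Without control 2 those of Krt19 (log2 fold change -1.86, adjusted p = 0.0518), Tac1 (4.21, 0.0542) and Prlr (3.31, 0.115) ended, and without control 3 those of Tac1 (3.23, 0.0685) and Prlr (3.53, 0.0710). With classes from the nearest control cells Tac1 (1.49, 0.674) and Prlr (3.30, 0.0904) ended. Prlr also ended without DKOΔendo 3 (3.07, 0.114) and with a sex term (3.10, 0.0533). Of the 45 called genes, Krt19, Npy, Smarca4 and Tac1 belong to a fixed list.

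Sst, which encodes somatostatin, passed when adjusted over its list alone in 1 of 5 sums of DKOΔendo tested against control, that of alpha-like cells. Fev precursor-like cells measured 375.3 ± 529 CPM (n = 2) against 53.7 ± 78.5 CPM in control (n = 3; log2 fold change 2.73, adjusted p = 0.0623 over the list alone), and the whole lineage, which contains the delta-like cells, 2053 ± 2255 CPM (n = 3) against 820.1 ± 352 CPM (n = 3; 1.32, adjusted p = 0.181 over the list alone). The SD exceeded the mean of DKOΔendo in these 3 sums. In the lineage sum DKOΔendo replicate 3 stood at 4641 CPM and the other two at 1002 and 514.1 CPM, within or near the 493.2 to 1193 CPM of the controls, so the lineage difference rests on that library. Slc30a8 in alpha-like cells lay between 36.9 and 45.5 CPM in the 4 Brg1Δendo;Brm+/- libraries and between 9.20 and 44.4 CPM in DKOΔendo, below all 3 controls (85.6 to 172.2 CPM).

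Cells with a UMI of Mki67 or Top2a at 3000 UMIs per cell were 2.03% of endocrine progenitor-like, 2.11% of Fev precursor-like, 1.74% of epsilon-like and 1.65% of delta-like cells, against 0.955% of alpha-like and 0.761% of beta-like cells, pooled over genotypes. These rest on few cells and their order turns by genotype: in DKOΔendo they were 2.22% of alpha-like (5 of 225), 1.54% of progenitor-like (1 of 65) and 1.12% of Fev precursor-like cells (1 of 89), and all 3 such delta-like cells came from Brg1Δendo;Brm+/-. Pooled, they were 34.5% of ductal and trunk-like, 34.3% of mesenchyme-like and 56.5% of acinar-like cells. A cluster within the ductal and trunk-like class was led by G2M phase genes.

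Of 81 ribosomal protein genes 74 lay lower in DKOΔendo than in Brg1Δendo;Brm+/- in the lineage, where the list was not called with an estimated correlation (adjusted p = 0.401) and 0 genes passed over the list alone. In acinar-like cells 79 of 81 lay lower, by a median of 147% (131 to 160%) of that in lineage cells. Acinar-like cells keep most of their Smarca4, so a library-wide difference between the groups, technical or from the germline Brm genotype, is a candidate explanation. The difference does not rest on DKOΔendo replicate 3, since 90.1% (80.5 to 95.6%) of it was left without that library.

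A fit of sums per class and library with class as a term called 138 genes (72 higher, 66 lower) in Brg1Δendo;Brm+/- and 407 (123 higher, 284 lower) in DKOΔendo against control, and 648 (119 higher, 529 lower) between the mutants, of 12810 tested by limma. Other splits of the libraries called up to 1372, 178 and 1186 genes in the same fit, and it made 61 false calls on simulated data, so its counts are not read as effects of genotype.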
